A study of Mus musculus with 4 samples.

How the data were processed

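RNA from cultured skin melanocytes of 2 wild-type C57BL/6 mice and 2 AhR knockout mice was amplified, labelled with biotin and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The deposited values are linear signal intensity, produced with MAS5, per the submitters' processing notes, which give no version. The values show the scaling that goes with that method, since the mean of the middle 96% of probe sets was between 500.2 and 500.3 on every array. Detection calls, background handling and any further filter by the authors are not given in the sources used here. All 4 columns of the table were used and 0 were left over. Scaling of this kind sets only the overall level, so a change that moves most transcripts one way would be divided out.

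Samples were assigned to groups by their titles, and each array is a separate animal. Titles number the animals 1 and 2 in both groups, with no statement of a shared litter, batch or day. Whether the numbers pair the arrays is therefore unknown, and no block was used in the main model.

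Of 22690 probe sets, 64 were controls, 20380 had a single gene symbol, 691 had several and 1555 had none in the platform annotation, and genes were named only from the first kind. Symbols were updated through gene identifiers to the RefSeq table of GRCm38.p6, which held 20351 of them. That table gives names and neighbours only, and no coordinates are printed, since no build belongs to these arrays. A gene was represented by the probe set with the highest mean, which gave 12393 genes. The values were converted to log2(signal + 16), so the folds of dim genes are understated. Genes in the top 60% by mean were tested, 7436 in all, with a lowest mean signal of 76.1.

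Groups were compared with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. All differences are AhR knockout minus wild type, with the SE from limma. An exact permutation of 2 against 2 arrays cannot fall below a share of 33.3%, so p-values rest on the limma model, which borrows the spread across genes. Gene lists were compared with all other tested genes by camera in limma with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. Lists with fewer than 5 tested members would have had no p. The correlation estimated from the data and the fry test were run beside it. With an estimated correlation, camera has only the 2 residual degrees of freedom of the 4 arrays. Few lists can then pass, whatever their correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

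The 23 gene lists, the position list of 50 measured genes on each side of Ahr, the model, the alternatives and the rule for naming genes were set before the data were examined. The lists were AhR target genes, AhR partners, pigment genes, melanocyte regulators, melanocyte growth factors, keratinocyte, fibroblast, leukocyte, Schwann and glial, and endothelial and mural markers, cell cycle, senescence, NRF2, interferon, antigen presentation, matrix and TGF-beta, cholesterol synthesis, lysosome, unfolded protein response, hypoxia, ribosomal proteins, mitochondrial respiration, and melanoma invasion and adhesion. They hold 455 entries, of which 401 were measured and 301 tested. The rule named Ahr, the 12 largest rises and the 12 largest falls among genes past the threshold with separated groups, and up to 4 members of each list by smallest p. Further members were named for the pigment, regulator, target and cell type lists. Dct, Pmel, Tyrp1, Atp7a, Mitf, Slc7a5, Pecam1 and Cyp1a1 were added to those in this way after their values were seen.

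The method was tested on simulated arrays of the same 7436 genes, with the moderated spread from limma, with 200 genes changed, over 20 runs. It recovered 21.9% of genes changed 2-fold, 94.1% at 4-fold, 99.9% at 8-fold and 100% at 16-fold, and 6.57% of calls were false. In lists with no change, at least 1 list was called in 3 of the 20 runs. The simulated noise was normal, drawn independently for each gene and alike on every array. No simulated array stood apart as AhR knockout 2 does in its control probe sets. The shares recovered therefore need not hold for the real arrays. Correlations estimated from the data were 0.46 for endothelial and mural markers and 0.34 for matrix and TGF-beta genes. For melanocyte growth factors the estimate was -0.016. These runs therefore cannot give the false call rate of lists with correlated members.

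Alternatives were quantile normalization, equal array medians, pseudocounts of 1 and 64, no filter and a top 40% filter, the mean of a gene's probe sets, every probe set by itself, eBayes without trend and robust eBayes, the title number as a block, an adjusted p under 0.10, folds of 1.5 and 3, and each array left out in turn. A covariate for the Gapdh 3' to 5' ratio was added after the data were seen.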

Results

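Gene expression was measured in melanocytes, the pigment cells of the skin, grown from tail epidermis of mice with and without the aryl hydrocarbon receptor (AhR). AhR is a ligand-activated transcription factor that responds to dioxins and to products formed by ultraviolet light. Cells from 2 wild-type C57BL/6 mice and from 2 AhR-deficient mice were grown for 6 to 8 weeks in serum-free melanocyte medium. Each of the 4 arrays holds the RNA of an individual mouse, so the replicates are biological, and n is 2 in both groups. The question put to the arrays was which transcripts of these cells differ when the receptor is missing. Every array had 22690 probe sets. The median signal was 96.8 and 98.4 in wild type 1 and 2, and 89.5 and 94.0 in AhR knockout 1 and 2. The trimmed mean was between 500.2 and 500.3 on every array. Arrays carry no count depth, and the number of arrays limits the precision.

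The targeted gene came first. In the knockout mice, exon 2 of Ahr is deleted. The brighter of the array's Ahr probe sets read 825 and 874 in the wild-type arrays and 241 and 843 in the knockout arrays. Its log2 difference was -0.88 ± 0.53 (SE), with adjusted p = 0.37, so Ahr did not pass the test. The difference rested on a single array: it was -1.75 with AhR knockout 1 as the only knockout array, and -0.0103 with AhR knockout 2 as the only one. The dimmer Ahr probe set read 28.4 and 19.9 in wild type and 41.3 and 49.9 in knockout. Where these probe sets lie relative to exon 2 was not analysed here, and a probe outside the deleted exon checks no label.

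Cyp1b1 and Ahrr, known targets of AhR, fell in the knockout cells. Cyp1b1, an AhR-induced cytochrome P450 that metabolises hydrocarbons and steroids, fell most of all tested genes. Its signal was 1216 and 1410 in the wild-type arrays against 14.0 and 23.1 in the knockout arrays, a log2 difference of -5.27 ± 0.36 with adjusted p = 3.114e-04. Ahrr, which encodes the AhR repressor, fell from 202 and 242 to 30.8 and 23.3, a log2 difference of -2.47 ± 0.35 with adjusted p = 0.019. Tiparp, another known target, was lower by log2 -1.27 ± 0.42 without passing, with adjusted p = 0.14. Selenbp1 had a log2 difference of 1.45 and Slc7a5 of 1.09, and neither passed. Cyp1a1, the classical AhR target, stayed below the signal filter in these cells.

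Over the whole list of AhR target genes, 6 of the 8 tested members were lower and 2 were higher. Of these, 2 fell over all genes tested, and 3 fell and 1 rose when adjusted over the list alone. The camera test, which compares a list with all other genes, gave adjusted p = 0.077 over 24 lists, short of the threshold. Leaving out any single array brought it to between 0.0018 and 0.026. The fry test, which asks whether the members move on balance one way, gave adjusted p = 0.0036 downward, and camera with an estimated correlation gave 0.48. The list of AhR partner proteins, which also holds Ahr itself, had 5 of 6 tested members lower, with Ahr among the 5. Of these, 0 passed in limma and 1 had an unadjusted p under 0.05, with a camera adjusted p of 0.088 for the list. Hif1a, a hypoxia-responsive partner of the same protein family, was lower by log2 -1.25 with adjusted p = 0.11. Arntl and Ncoa1 were lower by log2 -0.74 and -0.62 with adjusted p = 0.28 and 0.34. The median of that list was -1.20 in AhR knockout 1, where Ahr read 241, and -0.35 in AhR knockout 2, where Ahr read 843.

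Among 7436 tested genes, 12 rose and 49 fell in AhR knockout cells at an adjusted p under 0.05. All 61 separated the groups, with both knockout arrays on the same side of both wild-type arrays, and their differences ran from 3.44-fold to 38.7-fold. A total of 1055 genes differed at least 2-fold with separated groups, 311 of them higher and 744 lower. Separation itself was found for 55.1% of tested genes, where a random split gives 33.3% on average. Genes on the same arrays are not independent, so this share is no test of genotype. Across genes, AhR knockout 1 correlated with wild type 1 at r = 0.931 and with AhR knockout 2 at r = 0.917. The wild-type arrays correlated with each other at r = 0.959. At an unadjusted p under 0.05, 566 genes were higher and 949 lower.

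The 12 largest falls, led by Cyp1b1, held secreted signals, matrix enzymes and blood vessel genes. Sema3e, a guidance signal for vessels and axons, fell from 371 and 728 to 54.4 and 22.9, a log2 difference of -3.36 ± 0.45. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, fell by 3.30 on the log2 scale, and Nox4, an NADPH oxidase, fell by 3.15. Lox, which cross-links collagen, fell from 591 and 865 to 73.2 and 62.1. Tgfb2 and Inhba, both of the TGF-beta family, fell by 3.07 and 3.01 on the log2 scale. Sox17, an endothelial transcription factor, fell from 1446 and 1531 to 365 and 76.4, and Adgrl4, an adhesion receptor of endothelium, fell by 2.89. Pmaip1, a p53-responsive inducer of cell death, fell by 2.95, and Tll1, a matrix-processing protease, fell by 2.90. Sncaip, a synuclein-binding protein, fell by 2.85. Cyp1b1 aside, their adjusted p lay between 0.015 and 0.049.

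The genes that rose included detoxifying enzymes, a cell adhesion molecule and small secreted proteins. Gsta4, a glutathione transferase, rose from 339 and 210 to 2902 and 2561, a log2 difference of 3.27 ± 0.39 with adjusted p = 0.015. Gsta2, of the same family, rose by log2 2.82 ± 0.48. Cdh1, the E-cadherin that joins melanocytes to keratinocytes, rose from 89.1 and 23.3 to 549 and 636, a log2 difference of 3.24 ± 0.47. Ttr, the thyroid hormone carrier transthyretin, rose by log2 3.17, and Agt, angiotensinogen, by 2.61. Kcnn4, a calcium-activated potassium channel, rose by log2 2.80, and Ckb, a creatine kinase, by 2.57. Fxyd7 rose by log2 2.46 and Tenm4 by 2.10. G0s2, an inhibitor of fat breakdown, rose by log2 2.08, Lyz1, a lysozyme, by 1.99 and Adhfe1 by 1.94. A dim Lyz1 probe set was flat, at 31.6 and 20.1 in wild type and 21.7 and 28.4 in knockout (log2 -0.019). Shared binding of the brighter ones with the related Lyz2 was not checked. Of the 24 genes named among the largest changes, 13 had more than a single probe set, and 0 had a probe set of opposite sign with a size of 0.5 or more. That count passes over flat probe sets.

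**Figure D1:**
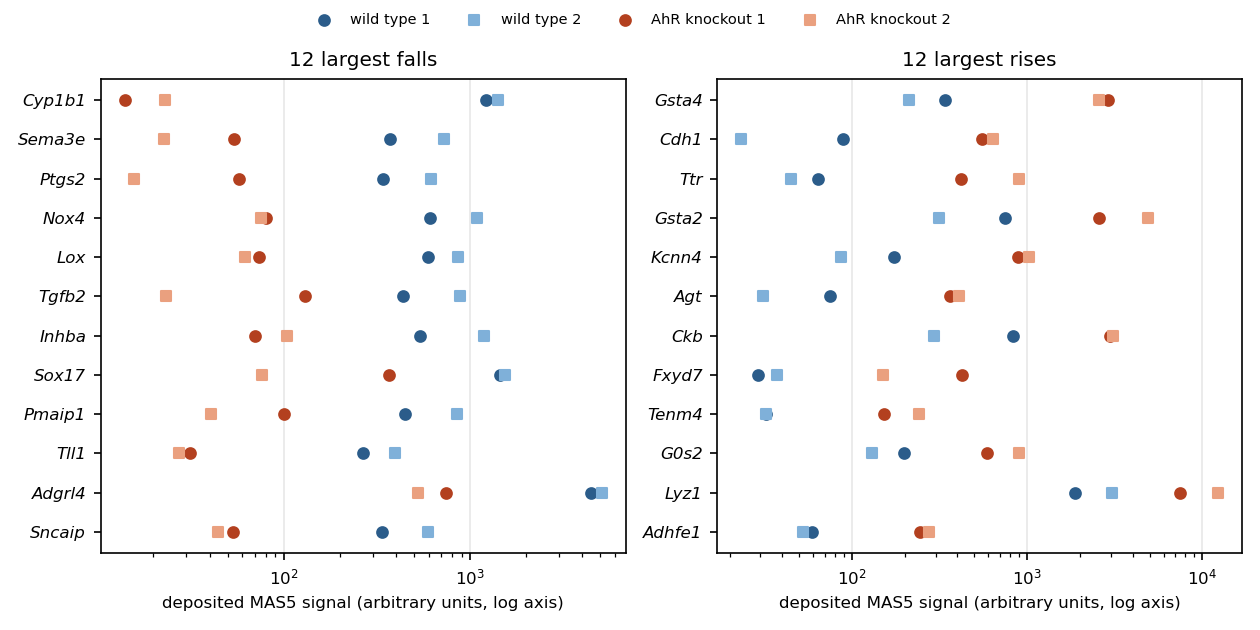
Deposited MAS5 signal (arbitrary units, log axis) of the 12 genes with the largest falls (left) and the 12 with the largest rises (right), with a point for each of the 4 arrays. Both knockout arrays lie on the same side of both wild-type arrays for every gene, and Cyp1b1 reads 14.0 and 23.1 in knockout against 1216 and 1410 in wild type.

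How many genes passed depended on the low-signal filter and on single arrays. Without the filter 0 genes rose and 1, Cyp1b1, fell in limma, with 842 and 1024 at an unadjusted p under 0.05, and without wild type 1, wild type 2, AhR knockout 1 or AhR knockout 2 in turn the calls were 164, 27, 1323 and 1000. With the array medians set equal, 32.1% of the calls were rises, against 19.7% as deposited.

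Control probe sets differed between the arrays. The ratio of the 3' to the 5' control probe set of Gapdh, which rises with shortened RNA or with amplification that favours the 3' end, was 2.13, 2.85 and 1.98 in wild type 1, wild type 2 and AhR knockout 1, and 11.9 in AhR knockout 2. The same ratio for actin was 7.89 and 8.71 in wild type, lower than both in AhR knockout 1, and 28.0 in AhR knockout 2. Spiked poly-A controls read 0.87, 1.15, 1.19 and 2.61 times the wild-type level in the same order.

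**Figure D2:**
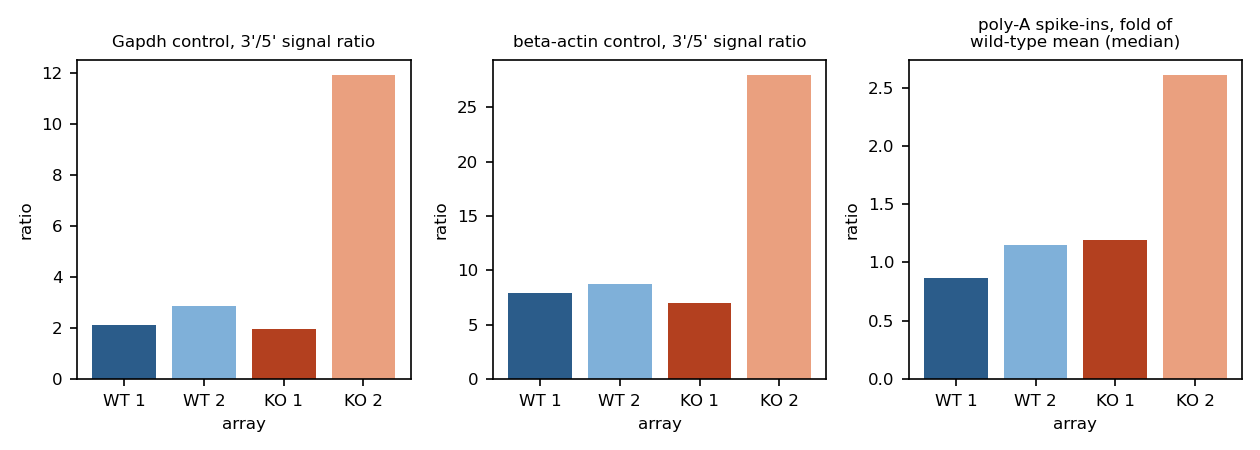
Ratio of 3' to 5' signal for the Gapdh and beta-actin controls, and signal of spiked poly-A controls relative to the wild-type mean, as a bar for each array (WT, wild type; KO, AhR knockout). AhR knockout 2 stands above the other 3 arrays in each panel, with ratios of 11.9, 28.0 and 2.61.

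Pigment genes were mostly higher in the knockout cells. Of 22 tested members, 17 were higher and 5 lower, with a median log2 difference of 0.44 (0.25 in AhR knockout 1 and 0.52 in AhR knockout 2), and 0 passed over all genes tested by limma, with 5 higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, 4 rose and 1 fell. In the same cultures 7 endothelial markers were lower, with a median of -1.94, against -0.53 for 19 further endothelial genes. Whether the share of melanocytes differed was not tested. Cited1, a transcriptional co-activator of pigment cells, read 803 and 317 in wild type and 2364 and 2169 in knockout, a log2 difference of 2.13 ± 0.46 with adjusted p = 0.059. Tyr, the tyrosinase that begins melanin synthesis, had a log2 difference of 1.20 ± 0.34 with adjusted p = 0.10. Slc45a2, a melanosome transporter, differed by 1.52 and Rab38, which carries pigment enzymes to melanosomes, by 1.47. Dct, Pmel and Tyrp1 differed by 0.56, 0.72 and 0.29, and Tyrp1 lay above both wild-type arrays in AhR knockout 2 alone. Atp7a, the copper pump that supplies tyrosinase, went the other way at -1.53. The brightest signals of any kind were higher in AhR knockout 2. The array maximum there was 38758.5, against 23507.1 and 24681.6 in wild type and 25678.6 in AhR knockout 1. Dct read 32201 in AhR knockout 2 and 20442 in AhR knockout 1, so the size for the brightest pigment genes depends on that array. The list was higher by camera, with adjusted p = 0.012, and adjusted p = 0.53 with an estimated correlation. Quantile normalization gave adjusted p = 0.083 and leaving out wild type 2 gave 0.12, so either ended the call.

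Regulators of the melanocyte lineage did not move one way. Of 14 tested, 4 were higher and 10 lower, with a camera adjusted p of 0.26, and Ptgs2 alone fell over all genes tested. Adjusted over the list alone, 2 fell and 1 rose. Sox10, a lineage transcription factor, differed by log2 1.54 with adjusted p = 0.11, and Kit, the receptor for stem cell factor, by -1.39 with adjusted p = 0.13. Snai2 differed by -0.85, and Mitf, the master regulator of pigment genes, by -0.41 with adjusted p = 0.52.

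Most of the few growth factors acting on melanocytes that were bright enough to test were lower. Of the list's 20 genes, 18 were measured and only 5 passed the signal filter, so the dimmer ones were not tested in either direction. Of the 5 tested members, 4 were lower, with a median log2 difference of -1.83. Over all genes tested by limma 0 passed, with all 4 at an unadjusted p under 0.05. Adjusted over the list alone, all 4 fell. Edn1, endothelin 1, read 1390 and 1379 in wild type and 516 and 207 in knockout, a log2 difference of -2.02 ± 0.45 with adjusted p = 0.064. Kitl, stem cell factor, differed by -1.97, Bmp4 by -1.83 and Igf1 by -1.58. The list was lower by camera with adjusted p = 0.0067, and adjusted p = 0.48 with an estimated correlation. Without the signal filter its adjusted p was 0.084. Endothelial markers, of cells that also make endothelin 1, were lower in the same cultures, with a median of -1.94 for 7 markers. For 19 further endothelial genes the median was -0.53.

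Matrix and TGF-beta genes gave the smallest camera p of all lists at the preset correlation. Of 21 tested members, 19 were lower, with a median log2 difference of -1.15. Lox and Tgfb2 fell over all genes tested, and 13 members fell when adjusted over the list alone. Thbs1, which activates latent TGF-beta, read 2876 and 2595 in wild type and 815 and 209 in knockout, a log2 difference of -2.67 ± 0.55 with adjusted p = 0.053. Ccn2, a target of TGF-beta signalling, differed by -1.43 with adjusted p = 0.069. Camera gave adjusted p = 4.176e-08, and adjusted p = 0.48 with an estimated correlation. Of 8 tested fibroblast markers 6 were lower too, and that list passed camera without the signal filter, with adjusted p = 9.511e-04. All 7 tested endothelial markers of the list were lower as well, with a median of -1.94. Of 19 further endothelial genes 14 were lower and 5 higher, with a median of -0.53. The matrix median was -0.87 in AhR knockout 1 and -1.24 in AhR knockout 2, the array with the high 3' to 5' ratios.

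Markers of blood vessel cells were lower in the knockout cultures. Of 11 tested endothelial and mural markers, 10 were lower and 1 higher, with a median log2 difference of -1.03. None passed over all genes tested by limma, with 5 lower and 1 higher at an unadjusted p under 0.05, and 5 fell and 1 rose when adjusted over the list alone. Emcn, endomucin, read 7391 and 10176 in wild type and 3321 and 1041 in knockout, a log2 difference of -2.21 ± 0.49 with adjusted p = 0.063. Cd34 differed by -2.19, Pecam1 by -2.08 and Tek by -1.67. Cspg4, a proteoglycan of pericytes and melanocyte tumours, differed by 1.72. Camera gave adjusted p = 0.0032, and adjusted p = 0.48 with an estimated correlation. The median was -0.89 in AhR knockout 1 and -1.78 in AhR knockout 2, and leaving out AhR knockout 2 ended the call, with adjusted p = 0.073, as did the top 40% filter, with 0.082.

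**Figure D3:**
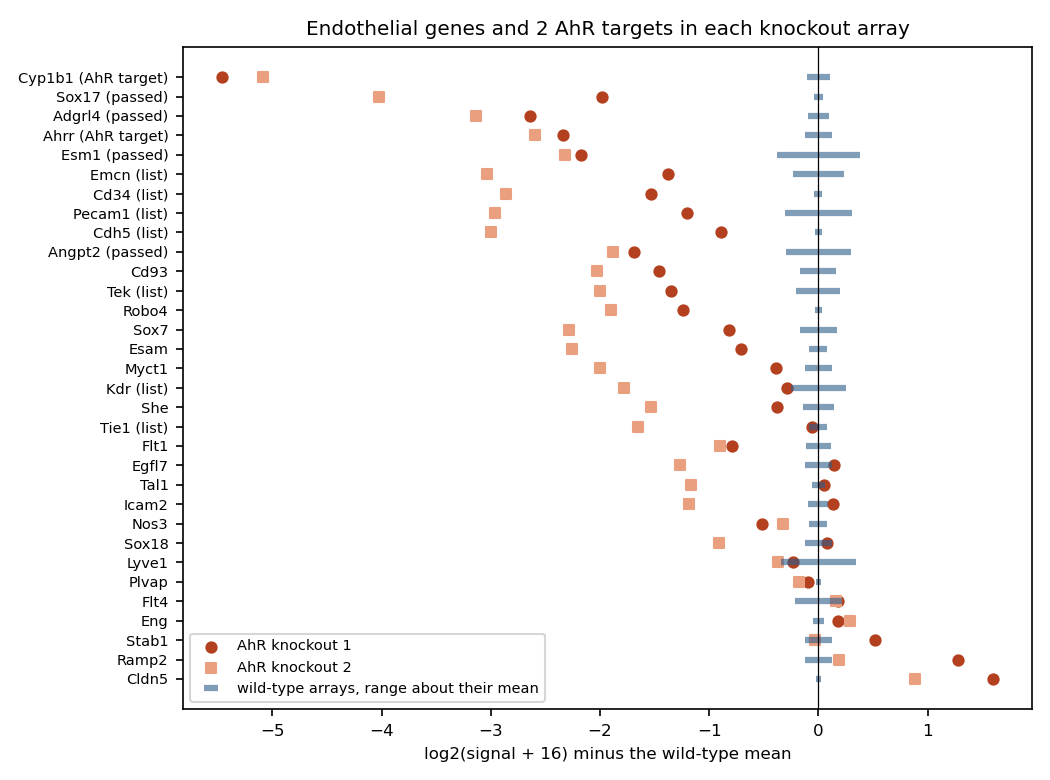
Difference in log2(signal + 16) from the wild-type mean in each knockout array, for 7 endothelial markers of the list, 19 further endothelial genes, 4 endothelial genes that passed the test and the AhR targets Cyp1b1 and Ahrr. Bars span the 2 wild-type arrays about their mean, and Cldn5, at a mean difference of 1.24, lies opposite to Emcn, at -2.21.

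In the main setting no other list of cell type markers was called. Of 8 tested fibroblast markers, 6 were lower, and Col3a1 fell by 2.29 on the log2 scale with adjusted p = 0.039 over all genes and 0.0012 over the list alone, while camera gave adjusted p = 0.12. The fibroblast list was called lower without the signal filter, with 9.511e-04, and with the mean of probe sets, with 0.023. Fbln2 was lower by log2 -1.16 with adjusted p = 0.15. Of 7 tested keratinocyte markers 4 were higher, with adjusted p = 0.60 for the list, or 0.030 without AhR knockout 2. These keratin genes were high in AhR knockout 1 alone, where Krt6a read 481 against 50.6, 39.6 and 56.2 elsewhere, and Krt5 read 305 against 31.4, 69.5 and 58.3. Of 6 tested leukocyte markers 4 were higher, with adjusted p = 0.13, or 0.044 with every probe set, and Lyz2 and C1qb differed by log2 1.79 and 1.04. Over the list alone, 2 of these rose. Of 8 tested Schwann and glial markers 5 were higher, with adjusted p = 0.15, or 0.030 with every probe set. S100b, also made by melanocytes, differed by 1.84 and rose over the list alone, and Ngfr differed by -1.03.

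Genes of growth and energy metabolism were higher. Of 16 tested cell cycle genes 12 were higher, with a median log2 difference of 0.63 (0.49 in AhR knockout 1 and 0.78 in AhR knockout 2), and 0 passed over all genes tested by limma, with 7 at an unadjusted p under 0.05, while 2 rose over the list alone. Cdc20, an activator of the mitotic exit ligase, differed by 1.57 and Ube2c, its partner enzyme, by 1.39, with adjusted p = 0.094 and 0.078. Camera gave adjusted p = 0.0067 for this list, and adjusted p = 0.48 with an estimated correlation. With the top 40% of genes kept, its adjusted p was 0.30. All 15 tested ribosomal protein genes were higher, with a median of 0.51 (0.29 in AhR knockout 1 and 0.72 in AhR knockout 2, the array with the high 3' to 5' ratios), 3 at an unadjusted p under 0.05 and 0 past the limma test, under camera adjusted p = 5.162e-04, and adjusted p = 0.48 with an estimated correlation. Quantile normalization left 11 of the 15 higher, with a median of 0.1698, and gave a camera adjusted p of 0.17. Of 20 mitochondrial respiration genes 17 were higher, with a median of 0.53 (0.41 and 0.60), 4 at an unadjusted p under 0.05 and 0 past the limma test, under camera adjusted p = 0.0042, and adjusted p = 0.48 with an estimated correlation. Quantile normalization gave a median of 0.29 and a camera adjusted p of 0.075 there. Rpl27 differed by 0.82, Rps9 by 0.75, Ndufa4 by 0.94 and Cox7a2 by 0.72.

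Genes of invasion and adhesion in melanoma split. Of 17 tested, 12 were lower and 5 higher, with a median of 0.0028 in AhR knockout 1 and -0.83 in AhR knockout 2. Cdh1 rose, and Vcan and Cav1, a matrix proteoglycan and a membrane scaffold protein, fell by 2.29 and 1.80 on the log2 scale. Adjusted over the list alone, 4 fell and 1 rose. Tnc, tenascin C, differed by -2.37 with adjusted p = 0.079. The list reached a camera adjusted p of 0.082, and passed without wild type 2 or AhR knockout 1, with 0.025 and 0.0027. It also passed under quantile normalization (0.016), without a filter (0.027), with every probe set (0.044) and with the replicate block (0.038).

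Oxidative stress genes under NRF2, a regulator of detoxification, were 10 higher and 6 lower of 16, with adjusted p = 0.18, or 0.040 without AhR knockout 2. Gsta4 rose, 2 rose over the list alone, and Gstm1 differed by 1.27 and Txnrd1 by -1.13. Their median of 0.29 turned to -0.01 under quantile normalization. Cholesterol synthesis genes were 11 higher and 5 lower of 16, with adjusted p = 0.077, or 0.043 without wild type 1. Fdft1 and Mvd differed by 1.37 and 1.31, and 2 members rose over the list alone. Senescence genes were 6 higher and 8 lower of 14, with adjusted p = 0.51, and Mdm2, the inhibitor of p53, differed by -1.88 and Gadd45a by -1.26. Over the list alone 1 fell.

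The remaining lists had 0 members past the limma test, over all genes or over the list alone. At an unadjusted p under 0.05, hypoxia genes had 1 higher and 3 lower, unfolded protein response genes 3 lower, interferon genes 2 lower, lysosome genes 1 lower and antigen presentation genes 0. Unfolded protein response genes were 6 higher and 12 lower of 18, or 9 and 9 under quantile normalization and 8 and 10 with equal medians, with adjusted p = 0.26. Lysosome genes were 10 higher and 5 lower of 15, or 8 and 7 under quantile normalization, with adjusted p = 0.50. Interferon genes were 8 higher and 4 lower of 12, with adjusted p = 0.88, and Rsad2 and Ifit2 differed by -1.28 and -1.20. Their median was 0.14, while the mean of -0.06 and the test pointed down. Hypoxia and glycolysis genes were 11 higher and 5 lower of 16, with adjusted p = 0.80, and Adm and P4ha1 differed by -1.73 and -1.40. Their median of 0.14 and camera pointed up, while the mean of -0.08 and fry pointed down. Class I antigen presentation genes were 3 higher and 7 lower of 10, with adjusted p = 0.94.

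The genes beside Ahr on its chromosome were 23 higher and 37 lower of 60 tested, with adjusted p = 0.082, or 0.027 without wild type 1 and 0.043 without AhR knockout 2. None passed over all genes tested by limma, with 14 at an unadjusted p under 0.05, while over the list alone 5 fell and 1 rose. Sec23a and Fam110c had log2 differences of -1.62 and -1.69. Of all 24 lists, 7 were called by camera, 0 with an estimated correlation, and 1, the AhR target genes, by fry. The estimated version has few residual degrees of freedom. For melanocyte growth factors, with an estimated correlation of -0.016, its unadjusted p was 0.084 against 0.0016 at the preset correlation. The lack of calls there therefore cannot be read as an effect of correlated members.

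**Figure D4:**
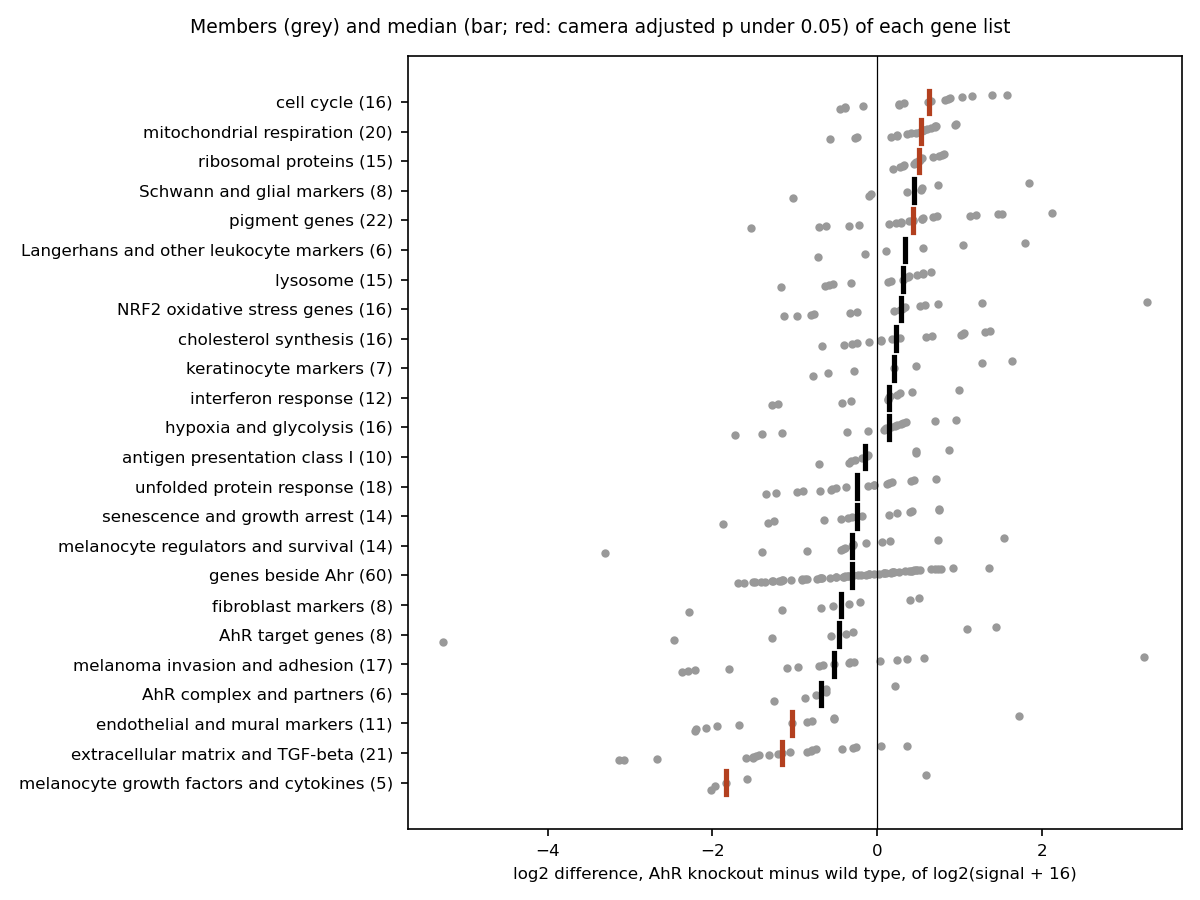
Log2 difference, AhR knockout minus wild type, of the tested members (grey) of the 24 gene lists, with the number tested in brackets and the median as a bar, red where camera gave an adjusted p under 0.05. Medians run from -1.83 for melanocyte growth factors to 0.63 for cell cycle genes.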

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

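Tests chosen only after the result was seen were the medians of the endothelial markers and of the further endothelial genes in AhR knockout 1, the intervals of the further endothelial genes, both comparisons with Cyp1b1 and Ahrr, and the test of the genes beside Ahr. The tests on the genes of AhR knockout 2 and on the level of the further endothelial genes were set before their results were seen, but the condition that the quartiles also pass the bound was added to the former afterwards.

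Control probe sets, outside the gene comparison, set AhR knockout 2 apart from the wild-type arrays: its Gapdh ratio of 3' to 5' signal was 11.9 and its actin ratio 28.0, its spiked poly-A controls read 2.61 times and its hybridization controls 1.61 times the wild-type level. Shortened RNA, or a difference in input or amplification, in this array alone may account for genes that differ there, so genes were chosen in AhR knockout 2 against a wild-type array and measured in AhR knockout 1 against the other. The 200 lowest genes had medians of -1.16 and -1.15 in the 2 pairings, with upper quartiles of -0.54 and -0.67, which argues against RNA quality or amplification of that array as the whole cause of the lower genes. For the 200 highest genes the medians were 0.50 and 0.63, with lower quartiles of -0.35 and 0.34. Both medians passed the bound of 0.5 set beforehand, narrowly, but neither lower quartile did. RNA quality and amplification are therefore left open there. The direction held in 174 and 192 of 200 lower genes and in 136 and 184 of 200 higher genes, and genotype stays among the open explanations, untested against culture or animal.

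The 7 tested endothelial markers of the list had a median of -1.21 in AhR knockout 1, with 6 of 7 below both wild-type arrays, which argues against RNA quality or amplification of AhR knockout 2 as the whole cause for these markers. For 19 further endothelial genes this is left open, since their median was -0.0994 in AhR knockout 1, with 9 below both wild-type arrays, and -0.91 in AhR knockout 2, with 14 below. Fewer endothelial cells may lie behind the lower markers, but over both arrays the 19 genes had a median of -0.53 with 73.7% lower, between the bounds set beforehand, and a second test put the 95% intervals of 13 of the 19 above the list's median of -1.94, with bounds set after the values were seen, so neither decided. The 19 leave out 4 called endothelial genes, Adgrl4, Sox17, Esm1 and Angpt2, and with these 78.3% were lower with a median of -0.56, within the bounds, but they were picked after they were seen to fall. The upper 95% limit of Cyp1b1, -4.47, was reached by 0 of 30 endothelial genes, called ones included. That argues against a loss shared by all endothelial cells as the cause of its fall. The 30 genes themselves ran from 1.24 for Cldn5 to -3.00 for Sox17, and a loss of only a subset of endothelial cells was not tested. For Ahrr, with 9 of the 30 at its limit of -1.70, a loss of endothelial cells cannot be told apart from the genotype.

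Genes beside Ahr may carry alleles of the strain in which the gene was targeted. Of 60 such genes, 14 had an unadjusted p under 0.05, 23.3%, against 20.4% of 7376 other genes, and a one-sided Fisher's exact test gave p = 0.33. With 60 genes a higher share was not excluded, and strain alleles cannot be told apart from the genotype itself.

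Probe sets that match several genes or none lie outside the gene comparison, and of 1052 tested, 3 were lower and 1 was higher in AhR knockout at an adjusted p under 0.05 in limma.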

How the results depend on the processing

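The Gapdh covariate was chosen after seeing the data, and all other settings were planned. The fit with this covariate leaves 1 residual degree of freedom. Its ratio was 11.9 in AhR knockout 2 and 2.85 or less in every other array, so calls with it rest largely on AhR knockout 1 against wild type. Cyp1b1 passed in each of the 15 alternatives that tested it (highest adjusted p 0.035), and Ahrr in all of its 15 but the one without a filter (0.19). Several other named genes passed about as often as Ahrr. The call was lost in 1 of 16 alternatives for Adgrl4 and Gsta4, and in 1 of 15 for Cdh1, Ttr and Nox4, among others. Some named genes passed less often: the call was lost in 9 of 16 alternatives for Sox17, and in 8 of 16 for Lyz1, G0s2 and Cav1. It was lost in 7 of 16 for Ckb and 7 of 15 for Tgfb2. The direction held for all called genes that were tested, 59 of 61 under quantile normalization, 58 with a pseudocount of 1, 26 with the top 40% filter and 54 with the mean of probe sets, except under every probe set, where the first probe set of 59 of 61 pointed the same way and that of 2 did not. Of the 61 calls, 20 remained under quantile normalization, 38 with a pseudocount of 1, 1 without a filter, 4 with the top 40%, 24 without wild type 2 and 56 without wild type 1. No detection calls were used, so how far dim signals stand above background was not analysed here.

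Genes higher and lower, 12 and 49 in the main setting, were 6 and 17 under quantile normalization, 18 and 38 with equal medians, 8 and 30 with a pseudocount of 1, 22 and 75 with 64, 0 and 1 without a filter, 2 and 2 with the top 40%, 7 and 22 with every probe set, 69 and 252 at an adjusted p under 0.10, and 497 and 1074 with the Gapdh covariate. With a single array left out they ran from 5 to 518 and from 22 to 805, where the lone array is assumed to vary like the other group. Genes with a 2-fold difference and separated groups were 1055, 1693 with every probe set, 2494 at 1.5-fold, 250 at 3-fold, and from 748 to 1741 with an array left out. The cause was not tested.

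Ahr, at -0.88, passed with the Gapdh covariate at -1.53, a setting that largely sets AhR knockout 2 aside. With an array left out, the Ahr difference ran from -1.75 to -0.0103. AhR target genes, at adjusted p 0.077, passed with every probe set (0.028), the Gapdh covariate (0.013) and fry (0.0036), and ran from 0.0018 to 0.026 with an array left out. Under the top 40% filter they pointed up (0.91), since Cyp1b1 and Ahrr are not tested there. Pigment genes, at 0.012, did not pass under quantile normalization (0.083), without a filter (0.084), with an estimated correlation (0.53) or with fry (0.38), and ran from 5.526e-04 to 0.12 with an array left out. The cause was not tested.

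Apart from those 2 called genes, directions that turned belonged to genes and lists that were not called. Cd68 was 0.0093 and Ifit1 -0.0040 with the Gapdh covariate, and Txnrd1 was 0.040 with the mean of probe sets. With an array left out, log2 differences ran from -1.71 to 0.012 for Snai2, -1.60 to 0.038 for Perp, -1.65 to 0.23 for Cd68, -0.29 to 2.28 for Ifit1 and -0.14 to 1.07 for Psmb10. Lists turned at adjusted p 0.34 for antigen presentation with the Gapdh covariate, at 0.45 for lysosome and 0.84 for hypoxia under quantile normalization, and for hypoxia at 0.99 without a filter and 0.98 with fry. With an array left out, adjusted p ran from 0.030 to 0.68 for keratinocyte markers, 0.60 to 0.73 for interferon, 0.26 to 0.64 for antigen presentation and 0.26 to 0.9962 for hypoxia. The cause was not tested.

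Of other lists not called in the main setting, some passed under other settings: fibroblast markers without a filter (9.511e-04) and with the mean of probe sets (0.023), and, with every probe set, leukocyte (0.044) and Schwann and glial markers (0.030) and genes beside Ahr (0.044). Melanoma invasion and adhesion passed under quantile normalization (0.016), without a filter (0.027), with every probe set (0.044) and with the replicate block (0.038). With the Gapdh covariate AhR partners (0.014), NRF2 genes (0.045) and genes beside Ahr (0.045) passed, and of the called lists, with the top 40% filter the endothelial (0.082) and cell cycle (0.30) ones did not pass.

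The replicate block, with title numbers as pairs, gave 431 higher and 940 lower genes on 1 residual degree of freedom, adjusted p 0.0059 for AhR target genes, and turned interferon (0.98) and antigen presentation (0.92). Same-numbered arrays deviated together across genes with r = 0.36, over only 2 pairs, so they share a number and no stated origin.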

Other observations

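The gene families and cell type levels given here were chosen after the values were seen. Of 15 families looked at by symbol, the glutathione transferases stood highest, with 14 of 16 tested members higher in AhR knockout, a median log2 difference of 0.51, and 14 of 16 higher under quantile normalization and equal medians too. Gsta4 and Gsta2 rose, and the related Gstm7, Gstm1 and Gstm5 had log2 differences of 1.82, 1.27 and 1.03 without passing, while Gsta3 had -0.44. Probe sets of these closely related enzymes were not checked for shared binding. Of 13 aldehyde dehydrogenases 11 were higher, 0 passed in limma, and Aldh1a3, which makes retinoic acid, read 60.7 and 36.4 in wild type and 192 and 199 in knockout. The count was 11 of 13 under both other scalings as well.

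Most tested membrane proteases and basement membrane genes had lower values, and neither family was tested as a group. Of 10 ADAM and ADAMTS proteases 9 were lower, 7 under quantile normalization and 8 with equal medians, and Adam12 fell from 315 and 392 to 63.8 and 75.1. Adam9, Adam10 and Adam17, which shed growth factors and receptors from the cell surface, had log2 differences of -1.45, -1.39 and -1.36 without passing. Of 8 basement membrane collagens and laminins 6 were lower, under every scaling, and 0 passed in limma, with Lama4 at -1.50 and Col4a1 at -1.06. The other families were claudins, semaphorins, IGF-binding proteins, S100 proteins, septins, serine protease inhibitors, histones, cytochromes P450, thrombospondins, integrins and cadherins, with medians between -1.88 and 0.37.

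Some endothelial transcripts were bright in every culture of these melanocyte preparations, wild type included, and others were dim. Signals of different probe sets are not on a common scale, so bright and dim do not rank these transcripts by abundance. Lyve1, a receptor of lymphatic vessels, read 7177 and 11546 in wild type and 7727 and 7026 in knockout, and Plvap, of vessel diaphragms, read 3237 and 3122 against 2966 and 2803. Neither passed, with log2 differences of -0.30 and -0.14, and Cldn5, a tight junction protein of endothelium, read 1510 and 1555 against 4688 and 2845, a log2 difference of 1.24 with adjusted p = 0.11. Flt1 read 124 and 148 against 71.9 and 65.2, Nos3 read 105 and 91.8 against 74.9 or less, and Vwf, of endothelial storage granules, stayed below the filter, at 25.8 or less in every array. Krt14 and Krt17, keratins of basal and wounded epidermis, read 539 and 291 in AhR knockout 1, with Krt14 at 30.8 or less and Krt17 far lower still in every other array.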
